A study of Mus musculus with 8 samples.

How the data were processed

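Whole left kidneys of 8 male mice aged 40 weeks were profiled by RNA sequencing of poly-A selected RNA, 4 mice homozygous for a deletion in C1qtnf1 (the gene of the secreted protein CTRP1, called KO here) and 4 wild-type littermates (WT). Each library came from a different mouse. Mice were assigned to groups by the genotype in the labels, and replicate numbers only name the mice within a group. No label tied a KO mouse to a WT mouse by litter, cage or day, so no pairing was used.

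The authors deposited 1 table with a column per mouse and no unit in its header. Its values were treated as FPKM (fragments scaled for gene length and for library depth), because the deposited columns had different totals and their low values were whole multiples of a step that became smaller with gene length. Per the submitters' processing notes, CASAVA, STAR 2.5, HTSeq 0.6.1 and DESeq2 were used with build mm10. The role of each tool, the annotation release, the filters and whether reads were counted by strand are not given in the sources used here. The table had 35275 genes and no columns of samples outside this study. Gene positions were taken from the GENCODE M21 annotation of the same build, which matched 34490 of them (97.8%) by identifier.

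The depth of each library was worked out from the FPKM steps, with the length of each gene fitted as well. At the exon length in M21, 5865 of the 22945 genes above 0 gave whole reads, so the read counts and gene lengths used rest on the fitted lengths. With fitted lengths, all 22945 genes came out as whole reads in all libraries within 0.002 reads. With the library totals shifted by up to 0.1%, 0.0% of 500 control genes did. The control genes were drawn from those with a mean FPKM of at least 1, so the recovery of lower genes was not checked. The library totals were 17884140 to 20344859 reads. The reads recovered in the table made up 99.94% to 99.97% of them. These reads were used for scaling factors, for counting error and for alternative tests. Intervals and floors cover counting error only, since PCR copies were not marked. The floor for a group with 0 reads was 3 reads over the group, and intervals for ratios of reads were exact binomial (Clopper-Pearson) at 95%.

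Before the data were examined, the main test was planned as a count test for raw counts. As the values were FPKM, limma 3.58.1 in R 4.3.3 was used in its place, on log2(FPKM divided by a scaling factor, plus a pseudocount of 1). Scaling factors were trimmed means of M values computed from the recovered reads, with 0.3 of the log ratios and 0.05 of the mean levels trimmed at each end, and lay between 0.93 and 1.04. Genes with a mean FPKM of at least 1 over the 8 libraries were tested, with empirical Bayes moderation (trend and robust options, statmod 1.5.0) and Benjamini-Hochberg adjustment at 0.05. Fold changes are differences on the log2(FPKM + 1) scale with their standard errors, and understate the change of low genes. FPKM are given as mean ± SD with n = 4 mice per group.

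There were 39 gene lists, of which 32 had at least 4 tested members. They covered pathways and cell types, except the immediate early and heat shock genes, which were listed as a quality check. They were tested with camera at a preset correlation of 0.01 between genes. The number of members past the threshold was counted over all genes tested and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives set at the same time. The mean of each list per mouse was also compared by an exact permutation test (two-sided), added after the data were seen. Genes within 10 Mb of C1qtnf1 were compared with the rest of the genome by Fisher's exact test (two-sided), because the deletion was made in 129S5 cells and bred onto C57BL/6J for more than 6 generations.

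The lists, the tests, most alternatives and the rule for named genes were set before the data were examined. The rule took C1qtnf1, up to 10 genes with the largest change in each direction among those past the threshold without overlap between groups, up to 4 members of each list past the threshold or otherwise the 2 with the lowest p, the 5 genes with the lowest p in a direction where fewer than 5 passed, and up to 5 called genes near C1qtnf1. Predicted genes without a usual symbol were counted but not named, and a few genes under the rule are not reported here. Other genes are said to have been chosen after their values were seen. Alternatives covered other scalings, other filters, a pseudocount of 0.1, limma-voom with and without quality weights, array weights, other thresholds and leaving out each mouse.

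The whole procedure was tested on simulated data made from the real means and depths, 10 sets of 12118 genes with 200 changed. The members of the fatty acid oxidation list were also lowered by 1.5-fold in these sets. Noise was drawn separately for each gene and library, so genes did not vary together and no library stood apart, unlike in the real data. In these sets the procedure found 40.1% of the genes changed by 1.5-fold, 78.8% of those changed by 2-fold and 96.4% of those changed by 4-fold. Unchanged genes made up 5.42% of the calls, and there were 0 calls at most in 10 sets with no changed gene. Figures and summaries were made with Python 3.11.15 (numpy, pandas, scipy and matplotlib).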

Results

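Kidney RNA of 4 mice without functional C1qtnf1 and 4 wild-type littermates was compared after long feeding of a diet with 60% of its calories from fat, begun at 6 weeks of age. The series set out to describe how the loss of CTRP1 changes gene expression in the kidney of older obese mice. The 8 libraries held between 17884140 reads (KO replicate 1) and 20344859 reads (WT replicate 4). In each, 19058 to 19467 genes were above 0.

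C1qtnf1, the targeted gene, fell from 5.42 ± 0.141 FPKM in WT to 0.61 ± 0.23 FPKM in KO (SD, n = 4 each). It lies on chromosome 11 from 118428203 to 118449963 (mm10). The 4 WT mice had 247 to 286 reads of it and the 4 KO mice 15 to 40, so each library matched its label. The log2 fold change was -1.99 ± 0.11 (SE, limma adjusted p = 2.5e-05). The deletion removed 679 bp, made up of the coding region of exon 4 and 162 bp of the 3' UTR. Reads of the other exons could still be counted, though values per gene do not show where the KO reads lay. An annotated gene on the opposite strand, Gm11747, shares exon bases with C1qtnf1, and its reads could not be separated.

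Among 12118 genes tested in KO and WT kidneys, 2 were higher and 3 lower in KO, the target included. Cyp4a14, a cytochrome P450 that hydroxylates fatty acids at their omega end, fell from 37.7 ± 8.89 to 8.32 ± 2.63 FPKM. BC018473 rose from 0.00274 ± 0.00547 to 13.9 ± 3.52 FPKM. St6galnac1, a sialyltransferase of mucin-type glycans, rose from 0 in every WT mouse to 3 ± 1.11 FPKM in KO. In each of these genes the 4 KO values lay on one side of the 4 WT values.

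**Figure D1:**
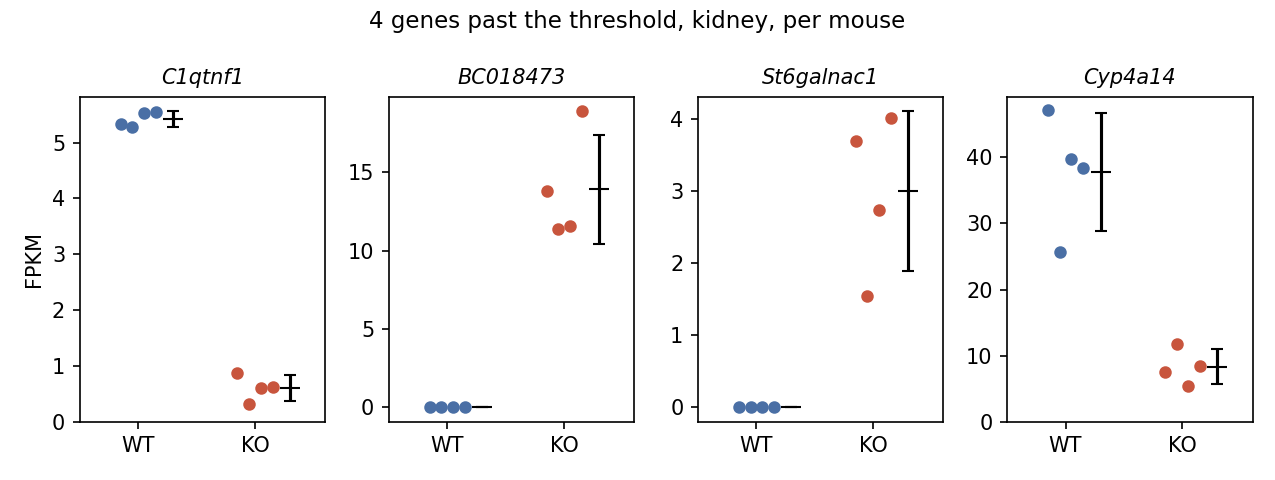
FPKM (vertical axis, from 0, a separate scale per gene) of 4 genes past the threshold in each mouse, WT in blue and KO in red, with the mean and SD of 4 mice in black. KO and WT values do not overlap in any of the 4 genes, and Cyp4a14 is at 37.7 FPKM in WT and 8.32 FPKM in KO.

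The log2 fold change of Cyp4a14 was -2.04 ± 0.23 (limma adjusted p = 0.011). For BC018473 it was 3.88 ± 0.14 (limma adjusted p = 6.8e-07), and for St6galnac1 1.96 ± 0.18 (limma adjusted p = 0.0021). The WT mice had 1 read of BC018473 in all and the KO mice 4974, a ratio of 5220 with a 95% interval from 936 to 206000. St6galnac1 had 0 reads in WT and 539 in KO. With WT put at the floor of 3 reads over the group, it was 188-fold higher in KO. That value depends on the floor and is not a lower bound, as the 95% interval of the ratio began at 153. Cyp4a14 lies on chromosome 4 from 115486200 to 115496142. Other Cyp4a genes lie beside it. Sequences were not compared, so it is not known whether reads were shared among these genes, which would make their levels uncertain. At an unadjusted p under 0.05 there were 476 higher and 266 lower genes, where chance gives 606 in all. Off chromosome 11 this held for 667 of 11076 genes (6.02%), and for 1283 (11.6%) without KO replicate 2. Genes do not vary independently, so chance alone can move these shares. The counts of 2 higher and 3 lower genes grew to 10 and 12 without KO replicate 2, to 15 and 4 without KO replicate 3, and to 39 and 31 with quality weights that gave KO replicate 2 a weight of 0.10. Cyp4a14 missed the threshold without WT replicate 1 (adjusted p = 0.11), WT replicate 3 (0.085), WT replicate 4 (0.066) or KO replicate 1 (0.07), while its log2 fold change stayed between -2.23 and -1.87 whichever mouse was left out.

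The genes next lowest in p did not pass the threshold. Among them Mxra7 was at 7.27 ± 0.273 FPKM in WT and 4.27 ± 0.637 in KO (limma adjusted p = 0.077). Acot3, a peroxisomal acyl-CoA thioesterase, was at 8.06 ± 0.815 and 4.52 ± 0.708 FPKM (limma adjusted p = 0.11). Slc6a12, a betaine transporter, was at 0.601 ± 0.13 FPKM in WT and 1.55 ± 0.246 in KO. Nupr1, a stress-responsive nuclear protein, was at 2.74 ± 0.0765 and 5.87 ± 1.44 FPKM, and the neuropeptide gene Npy at 1.58 ± 0.142 and 2.93 ± 0.459 FPKM. Mxra7 and Acot3 passed without KO replicate 2, Acot3, Slc6a12 and Nupr1 without KO replicate 3.

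The changed genes were more frequent in the region of the target on chromosome 11 than elsewhere. Of 178 genes tested within 10 Mb of C1qtnf1, 3 passed (C1qtnf1, BC018473 and St6galnac1), against 2 of 11940 elsewhere (Fisher's exact test, two-sided, p = 3.0e-05). With C1qtnf1 itself left out it was 2 of 177 (Fisher's exact test, p = 0.0012). BC018473 lies from 116752167 to 116759373 and St6galnac1 from 116765025 to 116775507, with no shared exon bases between them or with other annotated genes. Without KO replicate 2 the count near C1qtnf1 was 10 of 178 against 12 of 11940 elsewhere (Fisher's exact test, p = 2.0e-13). Fisher's test takes genes as independent, which close neighbours such as BC018473 and St6galnac1 need not be. These p-values can therefore overstate the evidence. Chosen after their values were seen, the further genes of that region were Smim6, Smim5, Mettl23 and Mxra7, lower in KO, and Tsen54, Cygb and Ubald2, higher in KO. With BC018473 and St6galnac1, they lay 1.57 Mb (Mettl23) to 2.61 Mb (Tsen54) from C1qtnf1, all on its lower-coordinate side. No gene nearer to C1qtnf1 passed without KO replicate 2. Smim6 was at 5.26 ± 0.569 FPKM in WT and 1.25 ± 0.282 in the 3 KO mice other than KO replicate 2, which had 4 FPKM. Tsen54 was at 10.5 ± 0.389 and 15.4 ± 0.735 FPKM, with 12.4 in KO replicate 2. Mettl23 shares exon bases with Jmjd6, Srsf2 and Mfsd11, and Cygb with Prcd, so their reads are uncertain.

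**Figure D2:**
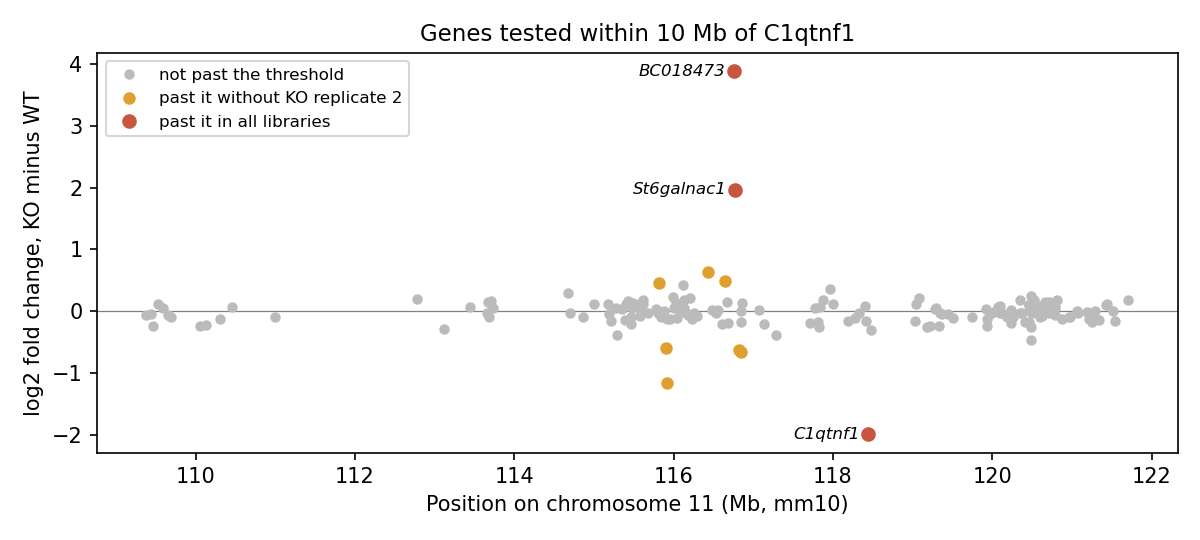
Log2 fold change of KO against WT (vertical axis) of each of the 178 genes tested within 10 Mb of C1qtnf1 by position on chromosome 11 (horizontal axis, Mb, mm10), red where past the threshold in all 8 libraries and orange where past it only without KO replicate 2. BC018473 at 3.88 and St6galnac1 at 1.96 stand apart from C1qtnf1 at -1.99.

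Genes of fatty acid oxidation and targets of the nuclear receptor PPAR-alpha were lower in KO as a group by the preset correlation. Of 21 measured members, 2 fell, Cyp4a14 among them, 0 rose and 19 did not pass, and 20 of 21 fold changes were below 0. Adjusted over the list alone, 3 fell, among them Cyp4a10 at 102 FPKM in WT and 61.9 FPKM in KO. The median log2 fold change was -0.17 (camera adjusted p = 3.5e-11). With an estimated correlation between genes the call was lost (adjusted p = 0.054), and fry gave an adjusted p of 0.018. Per mouse, the mean of the list lay from -0.45 to -0.27 in KO and from -0.06 to 0.06 in WT on the log2 scale. The list mean differed by -0.36 between KO and WT, and by -0.20 over the 19 members that did not pass. Less the mean of the proximal tubule transport list, which was called lower as well, these 19 differed by -0.05 (exact permutation p = 0.63), and without KO replicate 2 by -0.13 (exact permutation p = 0.029, the smallest possible).

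In all, 11 of the 32 lists passed with the preset correlation, 9 with higher and 2 with lower members. With an estimated correlation 0 passed by limma's camera, 3 being at an unadjusted p under 0.05, and fry called 1. Without KO replicate 2, 11 lists passed, 9 of them the same lists in the same direction. Camera's direction turned without that mouse in 8 lists, of which 0 had passed. These were the distal transport, lipogenesis, respiratory chain, antioxidant, vitamin D, endothelial, S3 segment, and B and plasma cell lists. Of the per-mouse list means, 4 separated KO from WT at the smallest p that an exact permutation test of 4 against 4 can give (p = 0.029), and 0 of 32 passed after adjustment (adjusted p = 0.23 for those 4). These were the fatty acid, urothelium, immediate early and heat shock, and male-biased lists.

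Markers of urothelium, the lining of the renal pelvis and ureter, were called higher in KO as a group by the preset correlation, but not by fry (adjusted p = 0.06). All 6 tested members had positive fold changes, 0 passed over all genes and all 6 passed adjusted over the list alone. Psca was at 1.92 ± 1.58 FPKM in WT and 9.29 ± 3.71 in KO, and the uroplakin gene Upk3a at 0.861 ± 0.417 and 3.16 ± 1.24. The median log2 fold change was 0.99 (camera adjusted p = 3.8e-10; adjusted p = 0.089 with an estimated correlation). Markers of principal cells of the collecting duct were also called (camera adjusted p = 0.044; adjusted p = 0.57 with an estimated correlation), with 4 of 5 positive and 0 past the threshold. Aqp2, the water channel of these cells, was at 203 ± 35.1 and 313 ± 61.8 FPKM and Fxyd4 at 12.3 ± 1.82 and 16.2 ± 3.8. That list did not pass without WT replicate 1 (adjusted p = 0.23), WT replicate 4 (0.13), KO replicate 1 (0.13) or KO replicate 2 (0.18), with no filter on low values (0.14), or with quality weights (0.48) or array weights (0.51).

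Injury, stress and immune lists were higher in KO by the preset correlation, and 0 of their members passed over all genes. In the tubular injury list (camera adjusted p = 4.3e-04; adjusted p = 0.42 with an estimated correlation) 9 of 10 were positive and 2 passed over the list alone. These were the keratin genes Krt18, at 8.06 ± 0.592 FPKM in WT and 14.9 ± 3.46 in KO, and Krt19, at 1.77 ± 0.727 and 5.09 ± 1.91. Collecting duct and urothelium also make these keratins, and the urothelium list had means of 0.69 to 1.54 in KO and the principal cell list 0.05 to 0.45. The mean of the tubular injury list was -0.00 in KO replicate 3, within the WT range of -0.04 to 0.04, and 0.35 to 0.44 in the other KO mice. The list missed the threshold with quality weights (adjusted p = 0.08) and array weights (0.12). The immediate early and heat shock genes had been listed as a quality check and not as a pathway. Of these genes 10 of 10 were positive (camera adjusted p = 4.5e-06, and 0.054 with an estimated correlation). Whether sample handling differed between the groups was not tested. Hspa1a was at 4.26 ± 1.14 and 11.7 ± 6.5 FPKM and Hspa1b, its near-identical copy, at 10.2 ± 2.49 and 30.3 ± 19.2. The mean of this list was 1.38 in KO replicate 2 and 0.47 to 0.58 in the other 3 KO mice. In the integrated stress and unfolded protein response list 11 of 13 were positive (camera adjusted p = 1.1e-04; adjusted p = 0.42 with an estimated correlation). Chac1, a glutathione-degrading enzyme, was at 0.748 ± 0.287 and 1.5 ± 0.243 FPKM and the asparagine synthetase gene Asns at 1.29 ± 0.447 and 2.19 ± 0.467.

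Interferon response genes had 15 of 15 positive fold changes (camera adjusted p = 5.1e-06; adjusted p = 0.51 with an estimated correlation). Isg15 was at 3.56 ± 0.679 FPKM in WT and 5.62 ± 1.4 in KO and Ifit3 at 8.26 ± 0.532 and 12.8 ± 4.27. KO replicate 4 had the highest mean of this list, 0.90, against 0.04 to 0.20 in the other KO mice. Class II antigen presentation genes followed that mouse as well, with a mean of 1.32 against -0.21 to 0.23 (camera adjusted p = 0.044; adjusted p = 0.70 with an estimated correlation). Without KO replicate 4 their direction turned (adjusted p = 0.85), and they did not pass without WT replicate 1 (0.15), WT replicate 4 (0.052) or KO replicate 3 (0.062), with no filter on low values (0.11) or with a pseudocount of 0.1 (0.051). H2-DMa was at 8.31 ± 0.404 and 12.9 ± 8.41 FPKM and H2-Ab1 at 150 ± 7.38 and 233 ± 156. Inflammatory cytokines and chemokines had 9 of 10 positive (camera adjusted p = 0.0013; adjusted p = 0.50 with an estimated correlation), with means of 1.02 in KO replicate 2 and 0.74 in KO replicate 4 but -0.09 and 0.06 in the other KO mice. Beside these 3 lists, the macrophage markers had a mean of 0.64 in KO replicate 4 and 0.23 in KO replicate 3, against -0.04 to 0.08 in WT and -0.14 and -0.08 in the other KO mice. Il34 was at 15.9 ± 1.59 and 21.6 ± 2.79 FPKM and Ccl2 at 0.624 ± 0.214 and 1.52 ± 0.674. This list missed the threshold without KO replicate 4 (adjusted p = 0.062) and with no filter on low values (0.25).

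Proximal tubule solute transporters were called lower by the preset correlation, with 17 of 20 fold changes negative and 0 past the threshold (camera adjusted p = 6.1e-04; adjusted p = 0.57 with an estimated correlation). The amino acid transporter genes Slc6a19, at 136 ± 11 and 105 ± 21.3 FPKM, and Slc7a9, at 78.3 ± 3.88 and 64.7 ± 4.65, had the lowest p. The list mean was -0.39 in KO replicate 2 and -0.09 to -0.05 in the other 3 KO mice, which lay within the WT range of -0.12 to 0.10. Male-biased kidney genes had 9 of 11 positive (camera adjusted p = 0.023; adjusted p = 0.57 with an estimated correlation) and did not pass without WT replicate 1 (adjusted p = 0.16) or KO replicate 2 (0.38), with no filter on low values (0.11), or with quality weights (0.61) or array weights (0.64). Slc22a7, an organic anion transporter, was at 5.02 ± 2.41 and 17.6 ± 7.83 FPKM and passed over the list alone. Odc1, the first enzyme of polyamine synthesis, was at 282 ± 10.3 and 354 ± 55.5 FPKM.

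**Figure D3:**
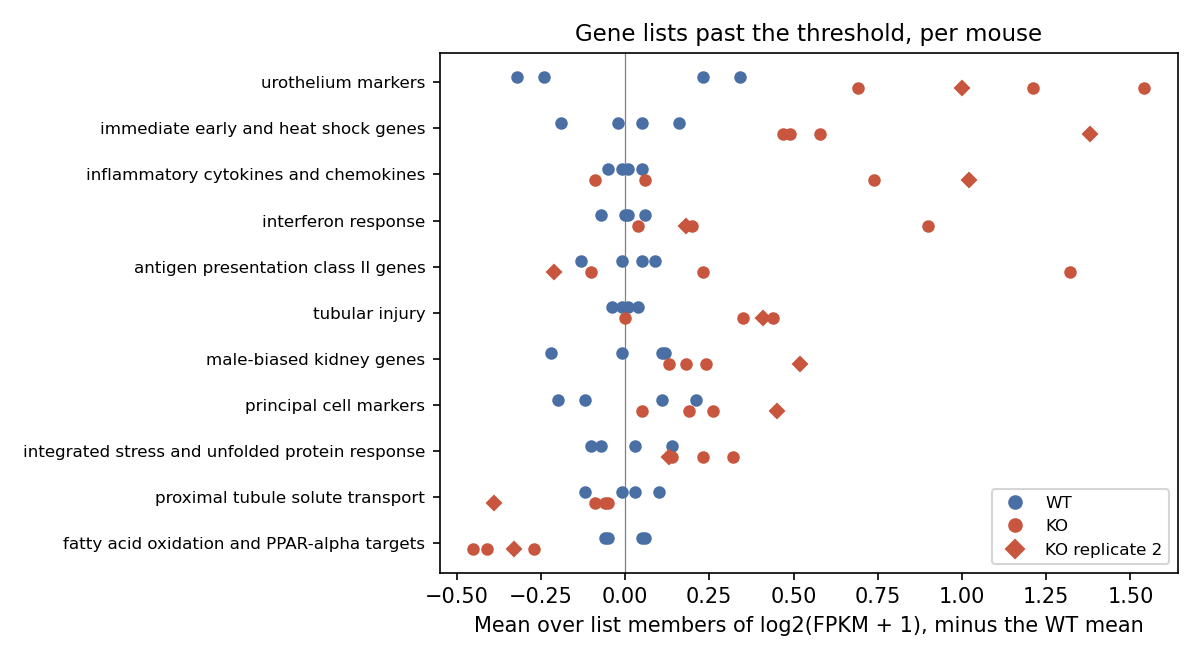
Mean over the members of each of the 11 called lists of log2(FPKM + 1) less the WT mean (horizontal axis, log2 units), 1 point per mouse, WT in blue, KO in red and KO replicate 2 as a diamond. For fatty acid oxidation the KO mice lie from -0.45 to -0.27, and for urothelium from 0.69 to 1.54.

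The other metabolic and transport lists did not pass and had 0 members past the threshold. For the renin-angiotensin-aldosterone axis 6 of 12 were positive (camera adjusted p = 0.27), with Enpep at 42 ± 1.92 FPKM in WT and 35.6 ± 4.42 in KO and Mme at 23.4 ± 4.25 and 17.7 ± 3.17. Distal sodium and potassium transport had 6 of 19 positive (camera adjusted p = 0.38), and 1 passed adjusted over the list alone. Its median turned from -0.09 to 0.02 without KO replicate 2. CTRP family members and adiponectin receptors had 4 of 7 positive (camera adjusted p = 0.89), with C1qtnf2 at 5.61 ± 0.419 and 4.31 ± 0.653 FPKM and Fam132a at 92.4 ± 5.08 and 103 ± 7.03. In the vitamin D, phosphate and calcium list (camera adjusted p = 0.75, median 0.02 but mean -0.06) 2 passed over the list alone in opposite directions. Cyp24a1, which inactivates vitamin D, was at 84.5 ± 14.4 and 147 ± 35.7 FPKM, and Cyp27b1, which activates it, at 4.41 ± 2.47 and 1.6 ± 0.466.

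Lipogenesis had 4 of 13 positive (camera adjusted p = 0.51), with Mlxipl at 42 ± 3.63 and 36.5 ± 6.99 FPKM and Dgat2 at 153 ± 6.97 and 136 ± 12. Cholesterol synthesis and uptake had 11 of 15 positive (camera adjusted p = 0.19), with Sqle at 11.6 ± 0.584 and 13.2 ± 1.2 FPKM and Fdps at 15 ± 1.29 and 17 ± 0.803. For the mitochondrial respiratory chain 18 of 24 were positive (camera adjusted p = 0.14), and the median turned from 0.11 to -0.06 without KO replicate 2. Ndufb8 was at 49.7 ± 1.16 and 58.4 ± 4.14 FPKM and Cox5a at 113 ± 7.11 and 131 ± 17.3. Gluconeogenesis and glycolysis had 6 of 12 positive (camera adjusted p = 0.87), with Pfkp at 7.42 ± 0.61 and 8.43 ± 0.126 FPKM and Pkm at 135 ± 7.37 and 149 ± 8. For extracellular matrix and fibrosis 10 of 20 were positive (camera adjusted p = 0.95), but the list passed without KO replicate 2 (camera adjusted p = 0.01; adjusted p = 0.67 with an estimated correlation). Tnc was at 1.08 ± 0.261 and 2.39 ± 1.03 FPKM and Acta2 at 13.6 ± 1.78 and 18 ± 3.36. The antioxidant and glutathione list had 9 of 15 positive (camera adjusted p = 0.73; median 0.04, or -0.04 without KO replicate 2), with Gsta2 at 189 ± 29.1 and 134 ± 12.7 FPKM and Hmox1 at 15.5 ± 0.959 and 17.4 ± 1.83. The circadian clock list had 6 of 14 positive (camera adjusted p = 0.38), with Per3 at 7.16 ± 0.825 and 5.33 ± 1.27 FPKM and Bhlhe41 at 2.15 ± 0.508 and 3.02 ± 0.537.

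Markers of the remaining kidney cell types did not pass. Camera gave an adjusted p of 0.79 for podocytes, 0.25 for endothelium, 0.49 for the S3 segment of the proximal tubule, 0.37 for the thick ascending limb, 0.44 for the distal convoluted tubule, 0.38 for intercalated cells, 0.075 for fibroblasts and pericytes, and 0.057 for macrophages. Without KO replicate 2 the median turned from -0.15 to 0.06 for endothelium and from 0.08 to -0.06 for the S3 segment. Without KO replicate 2 the macrophage list passed (camera adjusted p = 0.0063; adjusted p = 0.67 with an estimated correlation). Its mean was then 0.64 in KO replicate 4, 0.23 in KO replicate 3 and -0.08 in KO replicate 1, against -0.04 to 0.08 in WT. The podocyte gene Magi2 was at 2.91 ± 0.216 FPKM in WT and 2.41 ± 0.54 in KO. The endothelial genes Cdh5 and Kdr were at 11 ± 0.334 and 21.3 ± 1.43 FPKM in WT and 9.55 ± 2.26 and 17.8 ± 6.83 in KO. Acy3 and Slc5a8 of the S3 segment were at 1530 ± 200 and 47.5 ± 5.61 FPKM in WT and 1980 ± 257 and 41.5 ± 5.76 in KO. Umod and Egf of the thick ascending limb were at 1180 ± 114 and 330 ± 17.2 FPKM in WT and 1010 ± 132 and 271 ± 55.8 in KO. The distal convoluted tubule genes Slc12a3 and Tmem52b were at 324 ± 25.3 and 75.8 ± 2.92 FPKM in WT and 277 ± 86.4 and 61 ± 13.2 in KO. Kit and Foxi1 of intercalated cells were at 3.5 ± 0.44 and 9.2 ± 0.39 FPKM in WT and 2.99 ± 0.569 and 7.89 ± 1.39 in KO. The fibroblast and pericyte genes Gucy1a3 and Pdgfrb were at 5.03 ± 0.859 and 10.8 ± 1.54 FPKM in WT and 3.51 ± 0.989 and 8.13 ± 2.15 in KO. Csf1r and C1qc of macrophages were at 11.5 ± 1.09 and 19.9 ± 1.61 FPKM in WT and 13.1 ± 1.51 and 25.2 ± 8.74 in KO.

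Markers of blood and of neighbouring tissues did not pass either. B and plasma cell genes (camera adjusted p = 0.53) had Mzb1 at 1.84 ± 0.182 and 2.27 ± 0.226 FPKM and Igj at 11 ± 3.94 and 7.77 ± 5.41. Red blood cell genes (camera adjusted p = 0.49) had Hba-a2 at 54.1 ± 33.4 and 76.6 ± 16.7 FPKM and Hbb-bt at 38 ± 20.2 and 39.8 ± 3.26, both with near-identical copies. Fewer than 4 members were tested in 7 lists, which had no list test. These were cell cycle (3 tested), T cells (2), neutrophils (2), adipocytes (2), pancreas (1), adrenal (0) and skeletal muscle (0). Mcm2 was at 5.9 ± 0.622 and 5.9 ± 0.964 FPKM, Mcm5 at 1.92 ± 0.234 and 1.95 ± 0.606, Lck at 0.923 ± 0.276 and 1.35 ± 0.576 and Trbc2 at 1.26 ± 0.626 and 1.82 ± 0.917. S100a8 was at 1.07 ± 0.497 and 1.09 ± 0.468 FPKM and S100a9 at 0.978 ± 0.564 and 1.14 ± 0.849. Fabp4 was at 31.6 ± 4.52 and 35.8 ± 4.31 FPKM, Lipe at 5.4 ± 0.28 and 5.47 ± 0.604, and Cela1 at 59.6 ± 5.2 and 61 ± 5.93. In any library the highest adrenal marker was Star at 1.19 FPKM and the highest muscle marker Acta1 at 0.175 FPKM.

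KO replicate 2 stood apart from the other 7 libraries. The first principal component, with 50.2% of the variance, placed it at 42.6 and the others from -7.56 to -2.97. Its mean correlation across genes with the other libraries was 0.969, against 0.986 to 0.989, and genes are not independent replicates. Mitochondrially encoded genes made up 13.7% of its FPKM and 5.5% to 8.8% of the others. The second component, with 15.5% of the variance, had the WT mice from 3.32 to 12 and the KO mice from -16.9 to -0.992. Pairs of libraries in a group differed by 6.19 to 134 times the counting error in a chi-square test per degree of freedom, so no 2 libraries of the same group were copies of one another.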

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

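The tests of the 3 patterns weighed here were chosen after the result they bear on was seen, except the correlation of KO replicate 2 with the other KO mice. A mouse is listed here where its value lay far from those of the other 3 mice of its group. This held for 22 of 244 groups of 4 values (9.02%), where chance gives about 1 in 20, and 13 of the 22 were in KO replicate 2.

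KO replicate 2 had an FPKM total of 525275 against 438974 to 446601 in the other KO mice, a first principal component of 42.6 and a mean correlation of 0.969. Its list means were -0.31 for distal sodium and potassium transport, -0.39 for proximal tubule solute transport, -0.33 for lipogenesis, 0.21 for antioxidant and glutathione genes, 1.38 for immediate early and heat shock genes, -0.68 for endothelial markers and 0.4 for S3 markers. In FPKM it had Acy3 at 2360, Asns at 2.89 and S100a9 at 2.41, above the other KO mice in each.

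The pattern of KO replicate 2 was weighed against 3 explanations. A wrong genotype label is argued against by C1qtnf1 at 0.322 FPKM, below each WT mouse. The knockout itself as the source is argued against as well. Over the 285 genes off chromosome 11 that deviated by more than 1 log2 unit in this library, the correlation with the change in the other 3 KO mice, with different WT mice as the reference for each side, was 0.00 (95% bootstrap interval -0.11 to 0.12, across genes). RNA or library quality that changes with transcript length remains a candidate explanation, since the deviation of this library correlated with gene length at a Spearman rho of -0.59 across genes, against at most 0.24 in size in the others.

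The genes near C1qtnf1 were weighed next. Of the 35 splits of the 8 mice into 4 and 4, 1 gave as many near genes, the real one with 3, and the highest of the others gave 0, but the others had 0 changed genes anywhere, so this count does not test the clustering. Failure of 129S5 reads to align is argued against for the 5 genes that were higher in KO without KO replicate 2, because it can lower a count but not raise it, and for the 4 lower ones it cannot be told apart, as gene-level values do not show which exons lost reads. A 129S5 segment left around the deletion and an effect of the deletion on its neighbours cannot be told apart, because both place changed genes near C1qtnf1. With C1qtnf1 and KO replicate 2 left out, 9 of 177 genes near it passed against 12 of 11940 elsewhere (Fisher's exact test, p = 6.2e-12). These 9 lay 1.57 to 2.61 Mb from C1qtnf1, all on its lower-coordinate side. Genes so close together need not change independently, so that p-value can overstate the clustering. No nearer gene was called, though Engase, 0.03 Mb away, was lower in KO at an unadjusted limma p of 0.0053 in all 8 libraries. By distance, 3 of 25 genes within 1 Mb and 15 of 116 from 1 to 3 Mb were at an unadjusted p under 0.05 (Fisher's exact test, p = 1).

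The lower genes of fatty acid oxidation form the third pattern. The library that stood apart is argued against as the source for Cyp4a14, since it passed without KO replicate 2 (adjusted p = 0.0088), though its adjusted p ranged up to 0.11 when another mouse was left out, with a log2 fold change of -2.23 to -1.87 whichever mouse that was. Fewer proximal tubule cells are argued against for this gene, as the transport list had a median of -0.17 and no member below -0.36 while Cyp4a14 fell by 2.04. For the 19 members that did not pass (median -0.16) a smaller share of these cells cannot be told apart, because their mean less that of the transport list did not separate KO from WT (-0.05, exact permutation p = 0.63), although it did without KO replicate 2 (-0.13, exact permutation p = 0.029, the smallest possible). Feeding state at collection and the loss of CTRP1 itself were not tested apart.

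Over all genes, 1 of the 35 splits, the real one, gave as many as 5 changed genes and the highest of the others gave 0, but the 5 include the deleted gene and 2 near it. With the genes within 10 Mb of C1qtnf1 left out, 1 of the 35 splits gave as many as the real 2 changed genes. That was the real split, and the highest of the others gave 0. This is the lowest share that 35 splits can give, and the count was chosen after the data were seen. Both genes lost their call without WT replicate 1 or WT replicate 3. Chance is argued against for these 2 but is not excluded. For the gene lists chance is not excluded, since 12 of the 35 splits gave as many as the real 11 lists at the preset correlation, and the highest of the others gave 14.

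Among the other values far from their group, KO replicate 4 had H2-DMa at 25.4, Lipe at 6.37 and Chac1 at 1.87 FPKM. KO replicate 1 had Odc1 at 437 FPKM. WT replicate 1 had Enpep at 39.2 and Ccl2 at 0.945 FPKM and a mean correlation with the other libraries of 0.986 against 0.989 in the other WT mice. WT replicate 3 had a cholesterol list mean of 0.11 and BC018473 at 0.0109 FPKM, which is 1 read.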

How the results depend on the processing

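Limma-voom without quality weights, array weights, the pseudocount of 0.1 for single genes and lists, and the alternatives for the count near C1qtnf1 other than its window and the leaving out of C1qtnf1 were chosen after seeing the data. The planned DESeq2 Wald test and the surrogate variable were not run, and limma-voom was run on the recovered reads. C1qtnf1 kept its direction and its call in all 17 alternatives. The counts of 2 higher and 3 lower genes were 39 and 31 with quality weights and 29 and 28 with array weights, and all 5 genes kept their calls in both. They ranged from 2 to 15 higher and from 1 to 12 lower genes when 1 mouse was left out. The highest counts came without KO replicate 3 (15 higher) and KO replicate 2 (12 lower), and the lowest without WT replicate 1 or WT replicate 3 (1 lower). The count near C1qtnf1 was 12 with quality weights and 11 with array weights, and ranged from 3 to 10 with 1 mouse left out, 10 being without KO replicate 2. The 11 lists were 7 with no filter on low values, 0 with an estimated correlation and 1 with fry, and ranged from 8 to 15 with 1 mouse left out, 15 without WT replicate 3 and 8 without WT replicate 1. The cause of these shifts was not tested. Among single genes, 6 that were not called turned sign. With 1 mouse left out the log2 fold change ranged from -0.05 to 0.08 for Mcm2, -0.09 to 0.13 for Mcm5, -0.02 to 0.07 for Lipe, -0.10 to 0.21 for S100a8, -0.16 to 0.24 for S100a9 and -0.01 to 0.52 for Hbb-bt. By library size only, Mcm2 was at -0.01 and Mcm5 at -0.00. Lipe was at -0.01 with either kind of weights. S100a8 was at -0.01 with quality weights and -0.00 with array weights, and S100a9 at -0.23 and -0.16. For the class II antigen presentation list the adjusted p ranged from 0.005 to 0.85 with 1 mouse left out, and its direction turned without KO replicate 4 (0.85). At 17884140 to 20344859 reads and 4 mice per group, 40.1% of simulated 1.5-fold changes were found, so changes of that size can be missed. In the simulated sets no library stood apart, so in the real data larger changes can be missed as well. Psca, 4.91-fold higher in KO by mean scaled FPKM, did not pass (limma adjusted p = 0.15).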

Other observations

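The genes in this part were chosen after their values were seen. None of those in this paragraph passed in all 8 libraries, and each passed without KO replicate 2. Hacl1, a peroxisomal enzyme of alpha-oxidation, was at 17.1 ± 1 FPKM in WT and 12.6 ± 0.178 in the other 3 KO mice, with 9.73 in KO replicate 2 (limma adjusted p = 0.044 without that mouse and 0.16 with it). Cyp4a31, next to Cyp4a10 and Cyp4a14 on chromosome 4 and alike in sequence, was at 95.5 ± 5.67 and 69.4 ± 4.24 FPKM, with 88.2 in KO replicate 2 (limma adjusted p = 0.048 without that mouse and 0.72 with it). Acot3, which shares exon bases with 2 other annotated genes, had a limma adjusted p of 0.044 without that mouse and 0.11 with it. Ccnd1, the gene of cyclin D1, was at 78.1 ± 4.6 and 53.7 ± 7.38 FPKM, with 37.9 in KO replicate 2 (limma adjusted p = 0.044 without that mouse and 0.16 with it). Npdc1, Camk2n2 and Lrp11 had log2 fold changes of 0.47, 0.54 and 0.39 without KO replicate 2, and limma adjusted p of 0.13, 0.24 and 0.86 with it. Like Acot3, Hacl1, Ccnd1 and Npdc1 share exon bases with other annotated genes, so their reads are uncertain.

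KO replicate 2 had high levels of immediate early and stress genes. Cxcl1 was at 27.4 FPKM against a median of 0.328 in the other 7 libraries, Nfkbia at 136 against 24, Junb at 113 against 22.6, Egr1 at 17 against 2.7 and Fos at 7.79 against 0.798. Long transcripts were low in it, with a median length of 4769 bases among 154 genes more than 1 log2 unit lower and 1034 bases among 151 genes as much higher.

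The genes near C1qtnf1 called without KO replicate 2 did not all shift in that mouse. As a share of the change in the other 3 KO mice, its change was -0.16 for Smim5 and 0.15 for Smim6, against 0.95 for BC018473 and 1.42 for Mxra7. Tsen54 was at 0.65, Cygb at 0.33, St6galnac1 at 0.66, Mettl23 at 0.51 and Ubald2 at 2.18. All but BC018473 and St6galnac1 passed only with KO replicate 2 left out, which favours genes in which that mouse differed. The deviation of its library also went with gene length (Spearman rho -0.59). The shares therefore do not show whether that mouse lacked a change of the region.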
